A study of Mus musculus with 6 samples.

How the data were processed

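Chromatin immunoprecipitation with sequencing (ChIP-seq) measured where Ikaros, the zinc finger transcription factor encoded by Ikzf1, sat on the genome of mouse natural killer (NK) cells. The series held 6 samples, 3 wild type (WT) and 3 in which Ikzf1 was deleted in cells that express NKp46 (KO). Per the labels' protocols, splenic NK cells were expanded in IL-15 at 50 ng/ml, cells were fixed in 2% formaldehyde, chromatin was sheared to fragments of 100 to 200 bp, and 2 µg of antibody were used. The analysis rests on 3 peak lists, 1 per WT library. KO libraries were not analysed here, and no comparison with them was made. Whether the authors' peak calling used them as the control is not known. The labels do not say that the libraries came from separate animals or cultures, so the spread between lists may be technical.

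Per the submitters' processing notes, the authors used Subread, Picard, SAMtools, MACS2, edgeR 3.20.0 and the mouse build mm10; the notes give no roles for these tools. The control library, fragment extension, q threshold and gene annotation behind the lists were not given in the sources used here. Each list was called on its own library, per the peak names. Per the file headers, the authors gave each peak a fold enrichment, which is a linear ratio, and −log10 values of its p and q. The deposited score was the whole part of 10 times the −log10 q in 100% of peaks of each list. Distance to a gene, a biotype and a mark for transcription factor genes also came from the authors, per the file headers. The fold enrichment belongs to its own list and was used to describe and rank peaks within that list. Percentiles below are ranks of fold enrichment within 1 list, 100 being the strongest peak.

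Lists with several rows for a peak, 1 per overlapping gene, were reduced to 1 row per peak, from 800, 2414 and 1595 rows to 685, 2084 and 1342 peaks. Peak numbers ran to 726, 2134 and 1384, so 41, 50 and 42 numbers were not in the lists; those peaks were not analysed here. The lists hold no read counts, so the depth of each library is unknown. Clopper-Pearson intervals at 95% describe counting error over peaks, regions or genes only. Lowest −log10 q values were 1.15, 1.06 and 1.12 in the 3 lists.

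Peaks sharing at least 1 base were merged into regions. The number of shared regions was set against 1000 random placements of each list within its chromosomes, which ignore mappability and open chromatin. Gene positions came from the RefSeq gene table of the same build, with 21887 protein-coding genes. That table has no strand and no exons, so the planned distance to transcription start sites was replaced by the distance from a region's midpoint to the nearest of both ends of a protein-coding gene, with 1 kb as the limit. Each region was assigned to the genes whose span it overlapped, and otherwise to the nearest gene within 50 kb. These replacements were chosen after the files had been seen. Exons, introns and UTRs were not assigned. The planned search for the Ikaros motif was not run, since no genome sequence was used here. Of 2145 protein-coding gene names in the authors' lists, 2051 matched the table (95.6%).

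Gene lists were fixed before the data were examined: AP-1, other bZIP factors, the Ikaros family, NuRD and co-repressors, NK lineage transcription factors, NK surface receptors, cytotoxicity, cytokine receptors and JAK-STAT, survival, cell cycle, trafficking, NF-kappa-B and NFAT, Notch, and markers of T cells, B cells, myeloid cells, erythroid cells, neurons and liver. Ribosomal protein and olfactory receptor genes were taken by name, for 21 lists in all; the ribosomal name rule also took 11 genes that are S6 kinases or Rps19bp1. Each list's number of genes with a region in 2 or more lists was compared with 10000 random lists matched on gene domain length in 20 bins (2-sided permutation test, Benjamini-Hochberg adjustment over 21 lists). A domain was the gene span plus, on each side, up to 50 kb or the midpoint to the next gene. The random lists were not matched on gene activity, open chromatin or mappability. The AP-1 list, which the series title names, was also tested alone.

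Spearman's rho of fold enrichment between lists and the difference of median fold enrichment by location had 100000 permutations each, 2-sided, adjusted over 3 tests. Regions named in the text, apart from an item that is not reported here, were, by a rule fixed before the data were examined, the 15 with the highest mean percentile among those in all lists; up to 4 members of each gene list with a region in all lists; and the AP-1 genes, Ikzf1, Ikzf3 and Ncr1 whether or not they had a region. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. On simulated data, merging recovered 200 of 200 regions planted in all lists. The gene list test called 1.2% of unchanged lists and 100% of planted ones over 21887 genes. Planted lists all had the same size and the same number of genes with a region, so the 100% does not give the power for shorter lists. Alternatives changed the peak threshold, the overlap rule, the distance limits, the gene assignment, the list test and the lists used. Alternatives chosen after seeing the data were the authors' gene column, a random placement anchored on gene ends, the exact probability of the matched lists, and the ribosomal list without S6 kinases and Rps19bp1.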

Results

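Ikaros ChIP-seq peaks were listed for 3 WT libraries of mouse splenic NK cells expanded in IL-15, the cytokine that sustains NK cell growth. The lists of WT replicates 1, 2 and 3 held 685, 2084 and 1342 peaks (mean 1370, SD 700, n = 3). Median peak widths were 281, 292.5 and 294 bp, and median fold enrichments, as the authors gave them, were 5.10, 4.73 and 4.99. The first question was which sites the lists shared.

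Merging gave 2526 regions, of which 500 were in all lists, 584 in exactly 2 and 1442 in 1. Replicate 1, with the shortest list, had a partner in both other lists for 73.1% of its peaks (95% Clopper-Pearson interval 69.7 to 76.4). That share was 24.0% for replicate 2 (22.2 to 25.9) and 37.3% for replicate 3 (34.7 to 39.9). Replicates 2 and 3 alone shared 465 regions, against 76 for replicates 1 and 2 alone and 43 for replicates 1 and 3 alone. Random placement within chromosomes gave at most 1 region in all lists, and a mean of 1.85 regions in 2 or more lists against the 1084 observed. Placement at the same offset from another gene end gave at most 3 regions in all lists, and a mean of 26.7 and at most 43 in 2 or more. The permutation p was 9.99e-04 for each count under both placements, the smallest that 1000 placements can give. Keeping only peaks with a −log10 q of 5 or more left 206 regions in all lists and 462 in 2 or more. Without replicate 2 or replicate 3, the remaining pair shared 543 or 576 regions.

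**Figure D1:**
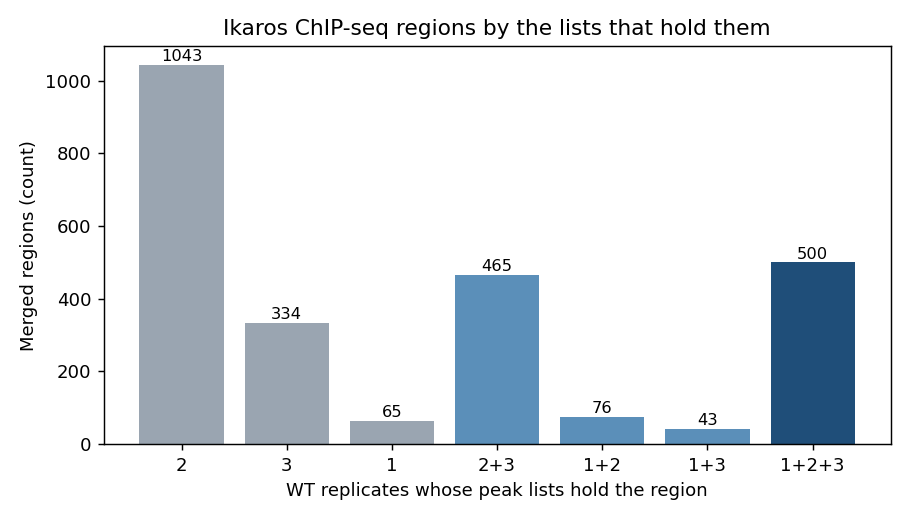
Bars give the number of merged regions (vertical axis, count) by the WT replicates whose lists hold them (horizontal axis), light grey for 1 list, mid blue for 2 and dark blue for 3. The largest bar is the 1043 regions of replicate 2 alone, followed by the 500 regions in all lists.

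The strongest regions in all lists lay mostly inside genes and away from gene ends. The highest mean percentile belonged to a region on chromosome 8, 46030703 to 46031613 (mm10), 1.23 kb beyond Lrp2bp (ENSMUSG00000031637), with fold enrichments of 46.4, 85.2 and 57.9 in replicates 1, 2 and 3. A region inside Tiam1, which encodes a Rac exchange factor, on chromosome 16, 89904958 to 89905892, had fold enrichments of 46.2, 80.4 and 70.7. On chromosome 9, 84970377 to 84971581, values were 40.8, 59.7 and 50.3, and the nearest protein-coding gene, Tent5a, was 349 kb away. A region 0.304 kb from Cox17, on chromosome 16, 38353067 to 38353712, had 37.2, 63.3 and 57.4. Of the 15 strongest regions, 9 overlapped a protein-coding gene and 1, that near Cox17, had its midpoint within 1 kb of a gene end. The overlapped genes were Tiam1, Mbd5, Cep192, Fcho2, Snx29, Clasp1, Kpna1, Dpp6 and Limd1, and these regions lay 11.9 to 281 kb from the nearer end of the gene. The other nearest genes were Pttg1ip2, Gp6 and Cypt1, the last 882 kb away. Of the 15 nearest genes, 0 belonged to the fixed lists of named genes. The authors' gene column names Gm48821 in place of Tent5a, Gm21987 in place of Cox17, Cldn12 in place of Pttg1ip2 and Gm25207 in place of Cypt1.

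Ranks of fold enrichment were related between lists. Spearman's rho across regions was 0.620 for replicates 1 and 2 (576 regions), 0.666 for replicates 1 and 3 (543 regions) and 0.698 for replicates 2 and 3 (965 regions). The permutation p, adjusted over 3 relations, was 1e-05 for each, the smallest that the permutations can give. Regions are not independent replicates.

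Regions in 2 or more lists gathered at the ends of protein-coding genes. Of 1084 regions, 557 (51.4%, interval 48.4 to 54.4) had their midpoint within 1 kb of a gene end, against a mean of 3.22% for regions placed at random. The share was 51.1%, 46.0% and 54.2% of peaks in the lists of replicates 1, 2 and 3 (mean 50.4%, SD 4.12, n = 3). Regions within gene spans but farther from an end made up 25.8% against 38.9% at random, and those over 50 kb from any gene made up 9.13% against 34.8%. The permutation p was 9.99e-04 for the gene end share, one-sided, the smallest that 1000 placements can give. Since strand was not used, starts and ends of genes were counted together. The share was 51.0% for the 500 regions in all lists and 46.5% for regions in 1 list, with an odds ratio of 1.20 and a Fisher exact p of 0.0864.

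**Figure D2:**
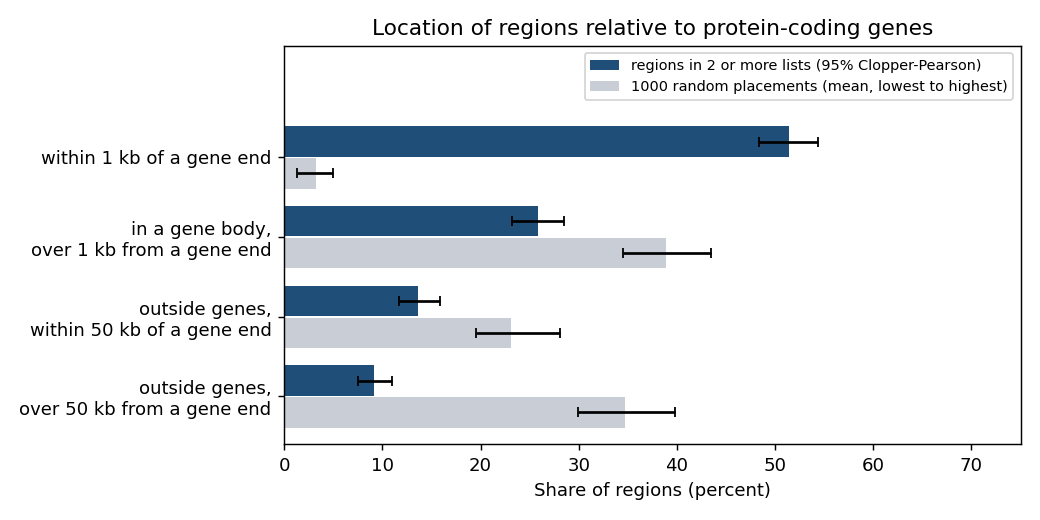
Bars give the percent of regions (horizontal axis) in each class of location relative to protein-coding genes (vertical axis), dark for the 1084 regions in 2 or more lists with 95% Clopper-Pearson intervals, and light for 1000 random placements with their lowest and highest values. Within 1 kb of a gene end the observed share is 51.4% and the random mean 3.22%.

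Peaks near gene ends were not the stronger ones. Median fold enrichment was 4.62 near a gene end and 4.84 elsewhere in replicate 2, with an adjusted permutation p of 7.2e-04. In replicate 3 the medians were 4.89 and 5.12, with an adjusted permutation p of 0.00943. In replicate 1 they were 5.08 and 5.10, with an adjusted permutation p of 0.849. With −log10 p in place of fold enrichment, the difference in replicate 2 no longer passed the threshold, at an adjusted permutation p of 0.181.

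The series title names AP-1, the dimers of FOS, JUN, BATF and ATF proteins, and the AP-1 genes were examined for nearby regions. Of 14 AP-1 genes, 3 had a region in 2 or more lists (21.4%, interval 4.66 to 50.8), namely Junb, Atf2 and Fos. The Junb region (ENSMUSG00000052837), on chromosome 8, 84976306 to 84976642, lay 0.267 kb from the gene, with fold enrichments of 3.98, 4.82 and 4.87 in replicates 1, 2 and 3. The Atf2 region, on chromosome 2, 73892648 to 73893141, overlapped an end of the gene and was in all lists. Percentiles in replicates 1, 2 and 3 were 10.1, 52.9 and 45.8 for the Junb region and 17.2, 45.7 and 44.4 for the Atf2 region. The Fos region (ENSMUSG00000021250), on chromosome 12, 85486004 to 85487047, lay 8.73 kb from the gene, with 5.07 and 5.68 in replicates 2 and 3. Jund, Batf3, Batf and Fosl2 had peaks in replicate 2 only, and Fosb, Fosl1, Jun, Batf2, Jdp2, Atf3 and Atf7 had none. Random lists averaged 0.659 genes, a ratio of 4.55, and the permutation p of the list alone was 0.049995, at the threshold. Adjusted over 21 lists the permutation p was 0.15, which did not pass, and the ratio rests on 3 genes. With regions in all lists the ratio was 6.86 with a permutation p of 0.0686, and with peaks of any list, 7 genes, it was 5.02 with a permutation p of 6e-04. Without replicate 2 or replicate 3 the ratio was 6.20 or 5.84, with permutation p values of 0.0828 and 0.0904, and by the authors' gene column 2 AP-1 genes, Junb and Fos, had a region (permutation p of 0.23).

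Other bZIP factors had 4 of 33 genes with a region, with an adjusted permutation p of 0.272; Maff had a region in all lists. In the Ikaros family, Ikzf1 was the 1 gene of 5 with a region in 2 or more lists. The authors' gene column does not name Ikzf1 there. That region, on chromosome 11, 11656396 to 11657456, lay 27.5 kb from Ikzf1 and had fold enrichments of 6.16 and 4.15 in replicates 2 and 3. Ikzf2 had a peak in replicate 2 only, and Ikzf3, which encodes Aiolos, had none. The family's adjusted permutation p was 0.83.

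NK lineage transcription factors were reached more often than genes matched on domain length alone. Of these factors 9 of 39 had a region, against 2.37 in random lists, a ratio of 3.79 with an adjusted permutation p of 0.0084. The fixed list also held Kmt2a, which encodes a histone methyltransferase rather than a lineage factor. Its region ranked highest among members with a region in all lists. It lay on chromosome 9, 44881262 to 44881712, at percentiles of 95.6, 93.8 and 96.7 in replicates 1, 2 and 3. Eomes, a T-box factor of NK cell maturation, had a region 1.98 kb away on chromosome 9, 118488112 to 118488510, at percentiles of 55.6, 92.2 and 75.5. Bhlhe40 and Irf2 also had regions in all lists. The authors' gene column names neither Eomes nor Bhlhe40. By that column 7 NK lineage genes had a region, a ratio of 3.26 with an adjusted permutation p of 0.0403. Cell cycle genes had 7 of 32 members with a region, against 1.34 at random, a ratio of 5.24 with an adjusted permutation p of 0.0021. Mcm3, a helicase subunit of DNA replication, had percentiles of 94.0, 96.4 and 94.4, and Cdk6, Cdkn2a and Ccnd2 had regions in all lists too. Their percentiles were 75.6, 93.1 and 78.8 for Cdk6, 45.1, 94.9 and 84.4 for Cdkn2a, and 11.7, 16.6 and 16.5 for Ccnd2.

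Cytokine receptor and JAK-STAT genes had 8 of 40 members with a region, against 1.99 at random, a ratio of 4.02 with an adjusted permutation p of 0.00945. Cish, a feedback inhibitor of cytokine signalling, had a region over 1 end of the gene on chromosome 9, 107296290 to 107297176, at percentiles of 97.1, 98.6 and 97.7. Tgfbr1 also had a region in all lists, a weaker one at percentiles of 24.2, 30.6 and 26.3. The NF-kappa-B and NFAT list, which also held EGR and NR4A genes, had 6 of 26 members with a region, against 1.36 at random. Its ratio was 4.41 with an adjusted permutation p of 0.0143. The 6 were Rel, Relb, Nfkb2, Malt1, Egr1 and Nr4a3, so no NFAT gene was among them. This list is called NF-kappa-B genes below. Rel, an NF-kappa-B subunit, and Egr1 had regions in all lists, at percentiles of 77.1, 77.5 and 83.8 for Rel and 26.3, 37.5 and 17.5 for Egr1. With regions in all lists, at a −log10 q of 5 or more, or without replicate 3, 0 of these 4 lists passed, with ratios of 4.41, 5.24 and 3.83 for NK lineage factors, 6.32, 5.24 and 5.52 for cell cycle, 2.12, 3.65 and 2.74 for cytokine receptors and 3.16, 1.81 and 2.73 for NF-kappa-B genes. Without replicate 2, cell cycle was the 1 that passed, at a ratio of 7.35, and the ratios of NK lineage factors, cytokine receptors and NF-kappa-B genes were 4.05, 1.96 and 2.88. With regions near a gene end only, cell cycle passed, and NK lineage factors, cytokine receptors and NF-kappa-B genes did not, with ratios of 3.40, 3.29 and 4.86 and adjusted permutation p values of 0.225, 0.225 and 0.122.

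Cytotoxicity genes had 5 of 32 members with a region, among them Ifng, with a region 21.6 kb away on chromosome 10, 118419071 to 118419430, and Gzmc. That list's ratio was 3.58 with an adjusted permutation p of 0.0966. NK surface receptors had 3 of 44 (adjusted permutation p of 0.952), with regions in all lists assigned to Klrb1c and Klra5, and Ncr1, which encodes NKp46, had none. Survival genes had 3 of 27 (adjusted permutation p of 0.641), trafficking genes 2 of 28 (0.952), and Notch genes 2 of 16, with Rbpj in all lists (0.779). NuRD and co-repressor genes had 0 of 17, with an adjusted permutation p of 0.952 and an upper limit of 19.5%.

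Lists of markers of other cell types held few genes with a region, and so few were expected that a count of 0 could not pass the test. T cell and B cell lists each had 0 of 20, erythroid 0 of 16, neuronal 0 of 25 and liver 0 of 24, and myeloid genes had 1 of 24, Csf2ra. Random lists averaged 0.969, 0.851, 0.628, 1.55, 1.01 and 1.04 genes in the same order, and upper limits of the shares were 16.8%, 16.8%, 20.6%, 13.7%, 14.2% and 21.1%. Adjusted permutation p values for these lists were 0.952, 0.952, 1, 0.779, 0.952 and 1. Ribosomal protein genes had 2 of 100, Rps19 and Rpl4, with an adjusted permutation p of 0.908. Olfactory receptor genes were reached less often than matched genes, 5 of 1110 against 41.6 at random, with an adjusted permutation p of 0.0021. Matching was on domain length only for every list, so differences in open chromatin or mappability were not accounted for.

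**Figure D3:**
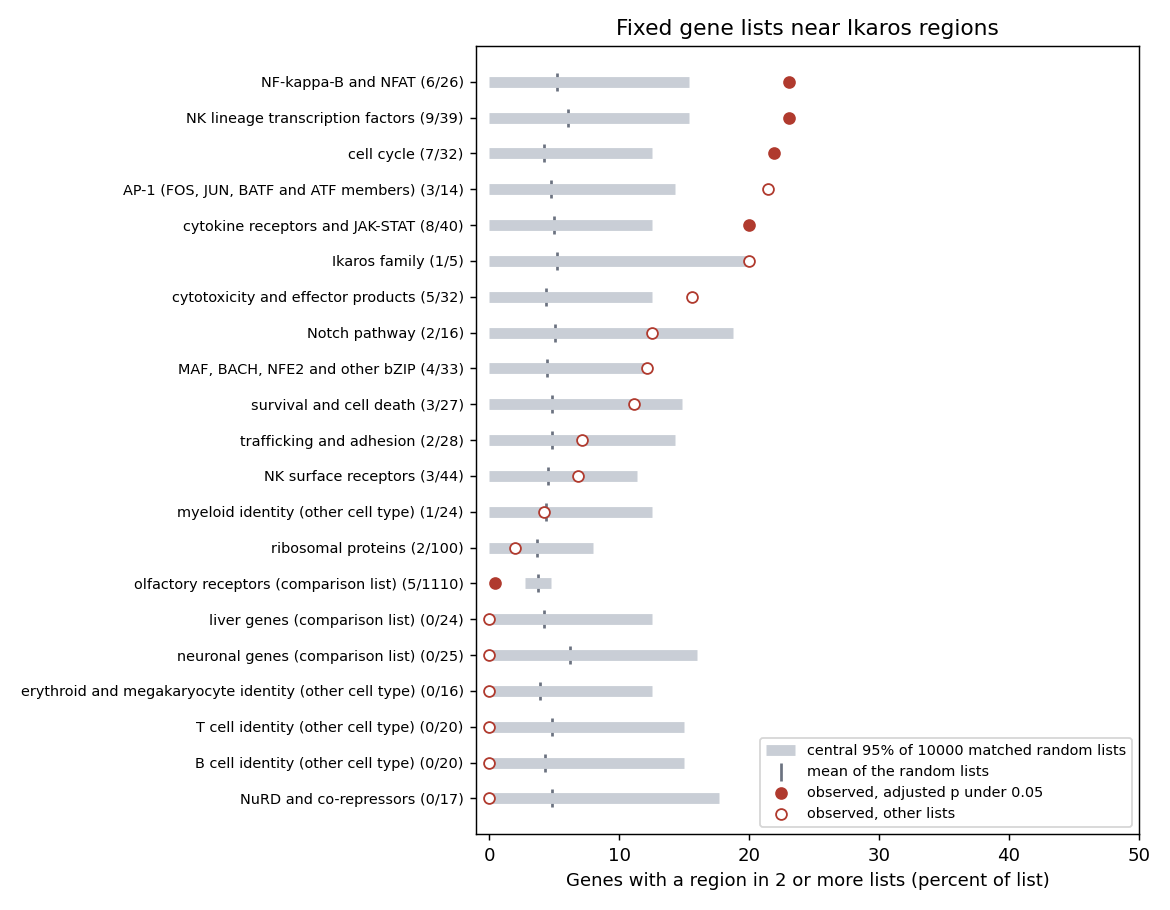
Points give the percent of genes of each fixed list with a region in 2 or more lists (horizontal axis), with the count beside the list's name (vertical axis); filled points passed an adjusted p of 0.05, and grey bars span the central 95% of 10000 matched random lists with their mean as a tick. NK lineage factors (9 of 39), cell cycle (7 of 32), cytokine receptors (8 of 40) and the NF-kappa-B and NFAT list (6 of 26) passed above the random lists. Olfactory receptors (5 of 1110) passed below. AP-1 (3 of 14) and cytotoxicity genes (5 of 32) also lie above their grey bars but did not pass.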

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

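No paired analysis was possible because the KO libraries were not analysed here and no result compared groups. The planned motif search was not run. Depth is unknown, so weak sites missing from a list cannot be told from unbound ones by depth. Causes of the changes below were not tested, except that stricter thresholds and shorter lists leave fewer regions by construction. The authors' gene column, the anchored placement, the exact probability and the narrower ribosomal list were chosen after seeing the data.

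Regions in all lists numbered 206 at a −log10 q of 5 or more, 73 at 10 or more and 318 with equal list lengths; those in 2 or more lists numbered 462, 158 and 584. Without 1 replicate, regions in 2 lists ranged from 543 to 965. Other overlap rules, or leaving out regions wider than 3 kb, gave 401 to 495 regions in all lists and 948 to 1079 in 2 or more. The gene end share stayed above random under every alternative run, from 45.7% (−log10 q of 5 or more) to 64.3% (5000 bp). All 3 rank relations kept their direction and side of the threshold. With −log10 p in place of fold enrichment, the difference of medians by location in replicate 2 was -0.234 (near gene ends minus elsewhere) and did not pass; replicates 1 and 3 kept their side of the threshold.

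The number of lists passing, 5 in the main test with olfactory receptors included, was 2 with regions near a gene end only, 1 with regions in all lists, 8 with peaks of any list, 1 at a −log10 q of 5 or more, and 1 to 6 without 1 replicate. Tested alone, the AP-1 list no longer passed near gene ends only (ratio 4.49, permutation p of 0.144) or with the nearest gene at any distance (4.14, 0.063). Nor did it pass with regions in all lists (6.86, 0.0686) or at a −log10 q of 5 or more (3.87, 0.46). It also did not pass by the authors' gene column (3.37, 0.23), without replicate 2 (6.20, 0.0828) or without replicate 3 (5.84, 0.0904). It passed within 10 kb of the gene body (5.11, permutation p of 0.0128), by the Fisher exact test (0.0263), with peaks of any list (5.02, permutation p of 6e-04) and without replicate 1 (5.24, permutation p of 0.0374). The exact p was 0.0493. Among the other lists taken singly, 18 values no longer passed and 4 newly passed, in the same direction.

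Ratios of lists that did not pass crossed 1 as follows. Near gene ends only, the Ikaros family and trafficking fell to 0, NK surface receptors were at 0.805 and ribosomal genes at 1.01. With the nearest gene at any distance, B cell genes were at 1.09. Within 10 kb of the gene body, trafficking was at 0.621 and erythroid genes at 1.89. With regions in all lists, the Ikaros family and survival were at 0, myeloid genes at 2.21 and ribosomal genes at 1.31. With peaks of any list, NuRD genes were at 2.72. At a −log10 q of 5 or more, the Ikaros family, survival and Notch were at 0, myeloid genes at 2.43 and ribosomal genes at 1.29. By the authors' gene column, the Ikaros family was at 0 and trafficking at 0.827. Without 1 replicate, the Ikaros family ranged from 0 to 4.20, survival from 0 to 2.61, myeloid genes from 1.09 to 2.05 and ribosomal genes from 0.594 to 1.25.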

Other observations

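The comparisons of AP-1 genes with the cell cycle and ribosomal protein lists and the test of partners of the shortest list were chosen after the result was seen; the permutation test of the AP-1 list was planned, and its reading against the error of the draws was set afterwards. The genes in the next paragraph were chosen after their values were seen.

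Genes that the authors marked as transcription factors made up 26 of 465 protein-coding genes at regions in all lists (5.59%, interval 3.68 to 8.09) and 60 of 1140 at regions in 1 list (5.26%), with a Fisher exact p of 0.807. Among them, Zfp260, a zinc finger gene, had a region over 1 end on chromosome 7, 30094681 to 30095174, at percentiles of 93.4, 98.2 and 97.5. Zxdc had one on chromosome 6, 90369322 to 90369662, at 94.2, 92.6 and 96.3. Nr3c2, which encodes the mineralocorticoid receptor, had one inside the gene at 88.9, 97.9 and 93.9. Regions at Nr3c1, the glucocorticoid receptor gene, were weaker, at 11.5, 20.6 and 11.3.

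There were 5 regions in all lists wider than 3 kb. The widest, on chromosome 9, 2999895 to 3038342, had percentiles of 28.8, 8.16 and 39.2. One on chromosome 2, 98662100 to 98667457, had 83.4, 2.11 and 57.1, and one on chromosome 14, 19415577 to 19419798, had 73.1, 6.09 and 59.0. One on chromosome 17, 39842899 to 39848943, had 51.5, 0.864 and 12.1. One on chromosome 11, 3100318 to 3103967, was among the lowest in each list, at 2.63, 0.576 and 0.894. Its −log10 q values were 2.43, 2.43 and 2.68. The other wide regions had high −log10 q values despite low ranks of fold enrichment in replicate 2. There the values were 26.7, 53.0, 51.1 and 36.8 on chromosomes 9, 2, 14 and 17, against a list median of 3.96. Mappability at these regions was not examined, so they cannot be read as broad Ikaros sites.

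Most regions, 1442 of 2526, were in 1 list, 1043 of them in the longest list, 334 in that of replicate 3 and 65 in the shortest. For the shortest list, list length alone stays open. Of its peaks, 90.5% (interval 88.1 to 92.6) had a partner in at least 1 longer list, which does not set it apart from the 90% asked of it. Of replicate 3's peaks, 71.9% (interval 69.4 to 74.3) had a partner in the longer list of replicate 2. That share argues against list length as the whole cause for replicate 3's regions, a reading made after the values were seen. A planned comparison at 685 peaks per list, 46.4% with a partner in both others, decided nothing, because that share could not exceed 73.1%. Peaks near the calling threshold may account for part of the regions in 1 list. The share of such regions below their list's median fold enrichment was 76.9% in replicate 1, 63.6% in replicate 2 and 76.3% in replicate 3. The same share was asked of every list, and replicate 2 fell short of it without reaching the bound against it. That explanation thus stays open for the pattern as a whole. Fold enrichment is an indirect measure here, since a peak of low fold enrichment can have a high −log10 q. No biological explanation was tested, since all lists are of 1 group.

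A candidate explanation for AP-1 genes near shared regions is that regions lie near many gene groups of these cells. Of cell cycle genes, the list with the highest ratio, 7 of 32 had a region, against 3 of 14 AP-1 genes (Fisher exact p of 1). With so few genes that test has little power. Ribosomal protein genes were reached less often, 2 of 100 (Fisher exact p of 0.013, not matched on domain length). Lists not set against AP-1 went both ways. NK lineage factors had 9 of 39, cytokine receptors 8 of 40 and NF-kappa-B genes 6 of 26. NK surface receptors had 3 of 44, trafficking 2 of 28 and NuRD genes 0 of 17. The comparisons thus do not decide whether this explanation holds. Chance choice of genes with domains of the same length cannot be told apart: the permutation p of 0.049995 lies at the threshold, with 2 standard errors of the draws at 0.00624, and the exact p was 0.0493. No biological explanation was tested, since the KO libraries were not analysed here.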
